A study of Homo sapiens with 4 samples.

How the data were processed

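The sources were the sample labels and 1 processed table of a public series, without its paper. The deposited table gives FPKM values that the authors made before deposit: per the submitters' processing notes, base calling used CASAVA 1.4, reads were aligned to the human genome hg38 with HISAT2 2.1.0, and Cufflinks 2.2.1 computed expression. The order and options of these steps, the scaling between libraries inside Cufflinks, the annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. The same holds for drug dose, time of exposure, numbers of reads and whether libraries came from separate cultures. The library text names a directional kit and ribosomal RNA depletion and also poly(A) fractions, and names different HiSeq instruments, so which applied to each library is not known. Trizol extraction and paired-end reads are stated.

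The table has 60595 genes by Ensembl identifier. The 4 FPKM columns were used, matched to the labels by name, and 12 other per-sample columns (confidence bounds and status) were not used. Symbols turned into dates by a spreadsheet (27) were restored through the Ensembl identifier, 58520 genes matched GENCODE release 29 and 60242 a current symbol. Locations are GENCODE release 29 on GRCh38. Of the tested genes 11350 share a locus with other genes in the table, so gene location was taken from GENCODE. Relative depth, estimated from the most frequent ratio between the values of low genes alone in their locus, was 1, 0.926, 0.866 and 0.963 in DMSO replicates 1 and 2 and paroxetine replicates 1 and 2. The titles do not say that a replicate number marks a shared day, so numbers were not treated as pairs, a choice fixed before the data were examined. The deviations of same-numbered libraries from their group means correlated at r = -0.0425 across genes.

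Genes at 1 FPKM or more in at least 2 of the 4 libraries were kept (15511). Paroxetine was compared with DMSO (2 libraries each) on log2(FPKM + 1) in limma 3.58.1 with the mean-variance trend and without robust variances, in a two-sided moderated test with 2 residual and 3.32 prior degrees of freedom and Benjamini-Hochberg adjustment over all tested genes. Genes at an adjusted p under 0.05 were called. At an unadjusted p under 0.05 there were 7609. By type, 2379 of 12210 protein-coding genes were called higher and 2874 lower, 143 and 126 of 1175 antisense RNAs, 100 and 61 of 652 lincRNAs, and 45 and 47 of 521 processed pseudogenes.

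Before the data were examined 42 gene lists were fixed, of which 40 had at least 5 tested members (1132 distinct genes). They were tested with camera, two-sided, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists. With an estimated correlation camera uses the 2 residual degrees of freedom, which leaves it little power. Camera compares a list with the other genes, while fry tests whether its genes move on balance one way and does not compare with other genes. With fry 15 lists were higher and 12 lower, which added serotonin genes (adjusted p = 0.00269), p53 targets (0.00230), metallothioneins (1.94e-05) and xenobiotic metabolism (0.0243) to the calls. Genes were named by a rule among called genes that have a symbol (not a clone or locus name), reach a mean of 1 FPKM in a group and have both paroxetine libraries on 1 side of both DMSO libraries: the 12 largest rises and falls, up to 4 members per list, and 6 genes fixed beforehand, together 166 genes, of which 163 were called. SLC6A4 was among the 6 and below the filter. Some results are not reported here. Members named for moving against their list were chosen after values were seen.

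The pipeline was tested on simulated data of this comparison (15433 genes, 200 changed, 2 libraries per group). Of changed genes 16.4% were called with the right sign at 1.5-fold, 53.7% at 2-fold and 75.8% at 4-fold, so genes not called are not shown to be unchanged. Of the calls 3% were false, 0 genes were called when none was changed, a list raised 1.5-fold was called and 0 random lists were. Noise was drawn independently for each gene, so the list checks do not cover correlation between genes. A far larger share of genes was called in the data (38.7%) than was changed here, so these rates may not carry over to the data.

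Alternatives were trimmed-mean scaling (trimming 30% of log ratios and 5% of mean values), quantile normalization, limma without the trend, no filter, a minimum of 5 FPKM, log2(FPKM + 0.1), replicate number as a replicate block, rescaling without mitochondrially encoded genes and abundant RNAs, each library left out, and a minimum change of 2-fold. All were fixed before the data were examined. Bootstrap intervals (95%) used 10000 resamples and permutation tests 100000 permutations. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.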

Results

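RNA sequencing measured gene expression in A375, an established human melanoma cell line, after exposure to paroxetine hydrochloride or to DMSO, the solvent control. Paroxetine is a serotonin reuptake inhibitor and a cationic amphiphilic compound. Each group had 2 libraries, and the dose and the time of exposure are not given in the sources used here. The deposited table lists 60595 genes as FPKM, a measure scaled for transcript length and library size, and 15511 genes that reached 1 FPKM in at least 2 libraries were tested. The FPKM values summed to 655607 and 655004 in the DMSO libraries and to 606197 and 640029 in the paroxetine libraries, with 15021 to 15223 genes at 1 FPKM or more per library. Numbers of reads are not in the table. Mitochondrially encoded genes held 13.1% and 12.9% of all FPKM in the DMSO libraries and 10.9% and 12.4% in the paroxetine libraries. Libraries of 1 group correlated at r = 0.983 (DMSO) and 0.982 (paroxetine) across genes on the log2 scale, and libraries of different groups at 0.941 to 0.942. Genes are not independent replicates. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values below are mean ± SD in FPKM, from DMSO to paroxetine, with n = 2 libraries per group, and fold changes are differences of log2(FPKM + 1) ± SE, which understates the fold change of genes with low values.

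The comparison asked which transcripts depend on paroxetine in these cells. Of the 12 genes named for the largest rises, 6 are given here and 6 further on, and FTH1 is added for its level. IL24, a cytokine gene of the interleukin-10 family, rose from 61.9 ± 4.10 to 639 ± 19.4 FPKM (ENSG00000162892, chromosome 1, 206897443 to 206904139), a log2 change of 3.35 ± 0.07. DDIT3, which encodes the stress transcription factor CHOP, rose from 13.5 ± 1.72 to 130.1 ± 3.49 FPKM (ENSG00000175197, chromosome 12, 57516588 to 57521737). SQSTM1, which encodes the autophagy receptor p62, rose from 182 ± 17.4 to 1585 ± 20.9 FPKM (ENSG00000161011, chromosome 5, 179806398 to 179838078). WIPI1, a gene of autophagosome formation, rose from 5.89 to 54.8 FPKM, GDF15, a stress-induced cytokine gene, from 1.250 to 13.7 FPKM, and CCN3, a gene of a matricellular protein, from 1.44 to 15.5 FPKM. FTH1, the heavy chain of the iron store ferritin, reached the highest level of the rising genes named here, from 1205 ± 42.2 to 6998 ± 1016 FPKM (ENSG00000167996, chromosome 11, 61959718 to 61967660).

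Some of the other genes among the 12 were less certain in origin. MRNIP (69.2 to 599 FPKM) shares exon sequence with SQSTM1 on the opposite strand, and FCMR (5.02 to 51.7 FPKM) ends next to IL24 on the other strand. The strand setting of the authors' counting is not given in the sources used here. FTH1P2 (5.15 to 47.5 FPKM) and FTH1P7 (1.18 to 12.5 FPKM) are processed pseudogenes of FTH1. LINC00520, a long non-coding RNA, rose from 0.0778 to 7.53 FPKM. RPL38P4, a processed pseudogene, was listed at 0 in both DMSO libraries and at 11.4 and 12.4 FPKM in the paroxetine libraries (adjusted p = 0.000284).

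The 12 genes named for the largest falls were of several kinds. ESM1, which encodes the proteoglycan endocan, fell from 216 ± 3.57 to 26.0 ± 0.564 FPKM (ENSG00000164283, chromosome 5, 54977864 to 55022671), a log2 change of -3.00 ± 0.05. THBS1, which encodes the matrix protein thrombospondin, fell from 281 ± 0.892 to 45.8 ± 1.27 FPKM (ENSG00000137801, chromosome 15, 39581079 to 39599466), MMP9, a matrix metalloproteinase gene, from 8.14 to 0.419 FPKM, and SERPINA3, a protease inhibitor gene, from 85.6 to 15.1 FPKM. Of the genes of replication origins and S-phase entry, MCM5 fell from 46.6 ± 3.44 to 6.85 ± 0.313 FPKM (ENSG00000100297, chromosome 22, 35400063 to 35425430), MCM10 from 15.7 to 1.76 FPKM and CCNE2, which encodes cyclin E2, from 16.9 to 2.22 FPKM. UHRF1, which maintains DNA methylation at replication, fell from 47.2 to 7.90 FPKM, and KRT81, a hair keratin gene, from 60.7 to 9.28 FPKM. IGF2BP2-AS1, an antisense RNA, fell from 6.50 and 7.97 FPKM in the DMSO libraries to 0 and 0.0633 FPKM. SNORA73B, a small nucleolar RNA, was listed at 7.03 and 17.9 FPKM in the DMSO libraries and at 0 in both paroxetine libraries, and SNRPGP2, a processed pseudogene, at 4.00 and 5.19 FPKM and at 0. SNORA73B (chromosome 1, 28508559 to 28508762) and SNRPGP2 (chromosome 18, 54406889 to 54407114) are short. How many fragments their values rest on is not known.

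**Figure D1:**
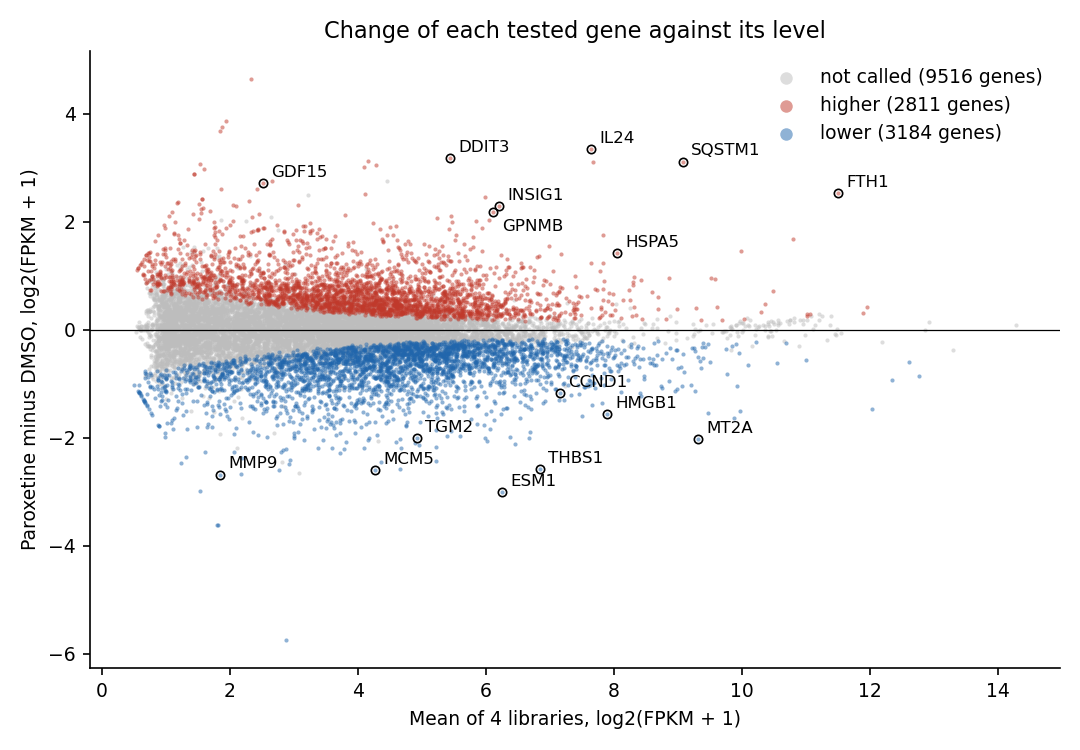
Each point is 1 of the 15511 genes tested, with its mean log2(FPKM + 1) over the 4 libraries on the x axis and the difference between paroxetine and DMSO on the y axis. The 2811 genes called higher are red, the 3184 called lower are blue and the 9516 not called are grey, and labelled genes include IL24 (3.35) and ESM1 (-3.00).

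With limma at an adjusted p under 0.05, 2811 genes were higher and 3184 lower, together 38.7% of the genes tested, and 572 of the higher and 684 of the lower genes changed at least 2-fold. The median log2 change of all genes tested was -0.0047. In 71.6% of the genes both paroxetine libraries lay on the same side of both DMSO libraries, against 33.3% by chance. Without 1 library the number of calls was smaller: 1502 higher and 1820 lower without DMSO replicate 1, 1539 and 1773 without DMSO replicate 2, 1442 and 2027 without paroxetine replicate 1, and 1472 and 2221 without paroxetine replicate 2. Exons of 38 of the 166 genes named by the rule overlap an expressed gene on the opposite strand, DDIT3, SQSTM1, FTH1, THBS1, CCNE2 and TGM2 among them, and those of 5 on the same strand, so that part of their signal can belong to the partner.

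The series title concerns genomic stability. Genes of replication, division and DNA repair were lower. All but 1 of the 48 DNA replication genes fell (47 fell, 0 rose; 47 fell adjusted over the list alone), with a median log2 change of -1.68. TYMS and TK1, of thymidylate supply, fell from 204 to 49.8 and from 94.2 to 23.3 FPKM, RRM2, of ribonucleotide reductase, from 182 to 41.0 FPKM and MCM2, of the replicative helicase, from 78.4 to 16.6 FPKM. Of 45 genes of mitosis 43 fell and 0 rose, with the same counts adjusted over the list alone and a median of -1.09. They included CDK1, the kinase that drives mitotic entry (113 ± 0.257 to 39.4 ± 0.385 FPKM), CDC20 (172 to 61.5 FPKM), UBE2C (244 to 105 FPKM) and ANLN (109 to 36.6 FPKM). Of 39 genes of homologous recombination and Fanconi anaemia repair 33 fell and 2 rose (35 and 2 adjusted over the list alone, median -1.11). The Fanconi genes FANCD2 and FANCI fell from 20.7 to 5.60 and from 68.0 to 22.3 FPKM and UBE2T, their ubiquitin-conjugating enzyme, from 114 to 33.1 FPKM. The 2 that rose, ATM (16.6 to 28.8 FPKM) and MUS81 (25.2 to 39.1 FPKM), were named after their values were seen, as were the other members named below because they moved against their list.

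Of 43 genes of mismatch, base and nucleotide excision repair and end joining, 23 fell and 2 rose, LIG4 and ERCC5 (24 and 4 adjusted over the list alone, median -0.38). UNG, which removes uracil from DNA, fell from 60.4 ± 3.98 to 13.3 ± 0.0746 FPKM, PARP1 from 107 to 51.9 FPKM, PRKDC, the catalytic subunit of DNA-dependent protein kinase, from 109.6 to 54.1 FPKM and MSH6 from 53.02 to 26.1 FPKM. The camera adjusted p was 4.61e-25 for replication, 1.75e-21 for mitosis, 3.18e-11 for recombination and 1.39e-05 for the other repair genes. For each of these lists adjusted p = 0.131 with an estimated correlation. The 35 genes of ribosome biogenesis and MYC targets moved the same way, with 23 lower and 1, POLR1C, higher (25 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 1.60e-07, adjusted p = 0.131 with an estimated correlation). NOP56, a small nucleolar ribonucleoprotein gene, fell from 147 to 57.4 FPKM, LYAR from 32.1 to 15.5 FPKM, CAD, of pyrimidine synthesis, from 38.1 to 20.3 FPKM and NCL, which encodes nucleolin, from 211 to 125 FPKM.

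Replication-dependent histone genes were higher, although genes of DNA replication were lower. Of 51 genes in the list 19 passed the filter. Of these 15 rose and 0 fell (17 and 1 adjusted over the list alone, median 1.14, camera adjusted p = 4.95e-06, adjusted p = 0.131 with an estimated correlation). Many of the 19 were under 1 FPKM in both DMSO libraries and passed the filter through the paroxetine libraries, which favours rises. The list kept its call with no filter. HIST1H2BD rose from 1.99 ± 0.0811 to 10.1 ± 1.90 FPKM (ENSG00000158373, chromosome 6, 26158146 to 26171349), HIST2H2BE from 2.04 to 10.2 FPKM, HIST1H1E from 0.275 to 4.63 FPKM and HIST1H4E from 0.109 to 3.45 FPKM. Histone genes are close paralogs, and whether reads were assigned to 1 of several matching genes is not given in the sources used here. A list of small non-coding and abundant structural RNAs was fixed as a check on RNA depletion in the libraries. Of its 10 tested members 3 rose, 0 fell and 7 were not called (the same adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.268 with an estimated correlation). The 3 that rose were the nuclear RNAs MALAT1 (73.4 to 217 FPKM) and NEAT1 (232 to 428 FPKM) and the mitochondrial ribosomal RNA MT-RNR2 (612 to 1684 FPKM). Of all 32 tested genes annotated as small RNAs, many of them 7SK and 7SL pseudogenes by symbol, 2 were called higher and 6 lower. The call of the list was lost in limma without the mean-variance trend (adjusted p = 0.0543; 0.00887 to 0.0543 over its alternatives).

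Genes of protein folding moved in opposite directions by compartment. In the endoplasmic reticulum, 24 of 39 chaperone and folding genes rose and 0 fell (27 rose adjusted over the list alone, median 0.46). HSPA5, which encodes the chaperone BiP, rose from 161 ± 7.72 to 429.9 ± 8.93 FPKM (ENSG00000044574, chromosome 9, 125234853 to 125241330), HERPUD1, of endoplasmic reticulum-associated degradation, from 27.7 to 115 FPKM, XBP1, a transcription factor of the unfolded protein response, from 30.8 to 80.5 FPKM and SELENOS from 24.5 to 59.8 FPKM. Of 36 heat shock proteins and cytosolic chaperones, 24 fell and 3 rose, DNAJB1, DNAJB4 and HSF2 (the same adjusted over the list alone, median -0.39). HSP90AA1, the inducible cytosolic HSP90, fell from 627 ± 19.7 to 295 ± 3.16 FPKM, and the chaperonin subunits CCT5, CCT3 and CCT7 fell from 347 to 204, from 257 to 155 and from 292 to 184 FPKM. Of 40 proteasome genes 25 fell and 1 rose, PSME4 (27 and 1 adjusted over the list alone, median -0.33). PSMA7 fell from 321 to 188 FPKM, PSMB2 from 132 to 78.6 FPKM, PSME3 from 113 to 67.9 FPKM and PSMC3 from 103 to 61.9 FPKM. The camera adjusted p was 9.81e-09 for the endoplasmic reticulum genes (adjusted p = 0.131 with an estimated correlation), 6.44e-06 for the cytosolic chaperones (adjusted p = 0.176 with an estimated correlation) and 1.38e-07 for the proteasome (adjusted p = 0.131 with an estimated correlation).

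Of 45 targets of ATF4, the transcription factor of the integrated stress response, 21 rose and 8 fell (23 and 8 adjusted over the list alone, median 0.26, camera adjusted p = 0.0131, adjusted p = 0.272 with an estimated correlation). DDIT3 was joined by PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2-alpha (21.4 to 81.1 FPKM), and CEBPB (25.5 to 61.3 FPKM). PSAT1, of serine synthesis, fell most, from 162 ± 1.28 to 66.0 ± 4.87 FPKM.

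Lysosomal and autophagy genes were higher. Of 51 lysosomal genes 33 rose and 2 fell, GUSB and ATP6V0C (36 and 3 adjusted over the list alone, median 0.37, camera adjusted p = 1.20e-08, adjusted p = 0.131 with an estimated correlation). GPNMB, a lysosomal and melanosomal glycoprotein gene, rose from 31.7 ± 2.73 to 147 ± 0.165 FPKM (ENSG00000136235, chromosome 7, 23235967 to 23275108), NEU1, a sialidase gene, from 8.44 to 36.4 FPKM, TPP1, a peptidase gene, from 22.9 to 49.6 FPKM and NPC1, of cholesterol export from lysosomes, from 34.5 to 73.8 FPKM. Of 41 autophagy genes 17 rose and 3 fell, ATG12, VMP1 and PIK3R4 (18 and 6 adjusted over the list alone, median 0.22, camera adjusted p = 0.00193, adjusted p = 0.175 with an estimated correlation). Besides SQSTM1 and WIPI1, the receptor gene OPTN rose from 14.2 to 41.3 FPKM and GABARAP from 165 to 275 FPKM. Among 10 markers of phospholipidosis, the storage of phospholipids that cationic amphiphilic drugs can cause, 4 rose and 1 fell (the same adjusted over the list alone, median 0.36, camera adjusted p = 0.0470, adjusted p = 0.280 with an estimated correlation). ASAH1, acid ceramidase, rose from 16.9 to 32.0 FPKM, and LSS and SLC2A3 also rose. The list overlaps others: ASAH1 is also in the lysosomal list, LSS in the cholesterol synthesis list and SLC2A3 in the hypoxia and glycolysis lists. The gene that fell was SERPINA3. The call of this list was lost without DMSO replicate 2 (adjusted p = 0.0759), without paroxetine replicate 1 (0.0806), with a minimum of 5 FPKM (0.129) and after rescaling without mitochondrial and abundant RNAs (0.0507), within a range of 0.0283 to 0.129 over its alternatives.

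Genes of cholesterol synthesis rose as a group. Of 28 genes of cholesterol synthesis and uptake, which SREBP2 controls, 25 rose and 2 fell, TMEM97 and PMVK (25 and 3 adjusted over the list alone, median 1.06, camera adjusted p = 6.38e-12, adjusted p = 0.131 with an estimated correlation). INSIG1, the sterol-regulated anchor of the SREBP pathway, rose from 32.5 ± 1.34 to 162 ± 2.61 FPKM (ENSG00000186480, chromosome 7, 155297776 to 155310235), a log2 change of 2.29 ± 0.06. HMGCS1 rose from 31.7 to 133 FPKM, and the later enzymes MSMO1 and LSS from 21.1 to 87.2 and from 12.3 to 36.1 FPKM. Of 21 genes of fatty acid synthesis and desaturation 12 rose and 1 fell, FABP5 (12 and 2 adjusted over the list alone, median 0.36, camera adjusted p = 0.000337, adjusted p = 0.175 with an estimated correlation). FASN, fatty acid synthase, rose from 87.7 to 234 FPKM, SCD, a desaturase gene, from 149 to 320.0 FPKM, ACSS2 from 10.9 to 39.0 FPKM and ACSL1 from 14.7 to 40.3 FPKM. Of 13 genes of cholesterol efflux and liver X receptor targets, APOE (0.755 to 4.29 FPKM) and CYP27A1 (5.53 to 11.6 FPKM) rose and 0 fell (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.650).

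**Figure D2:**
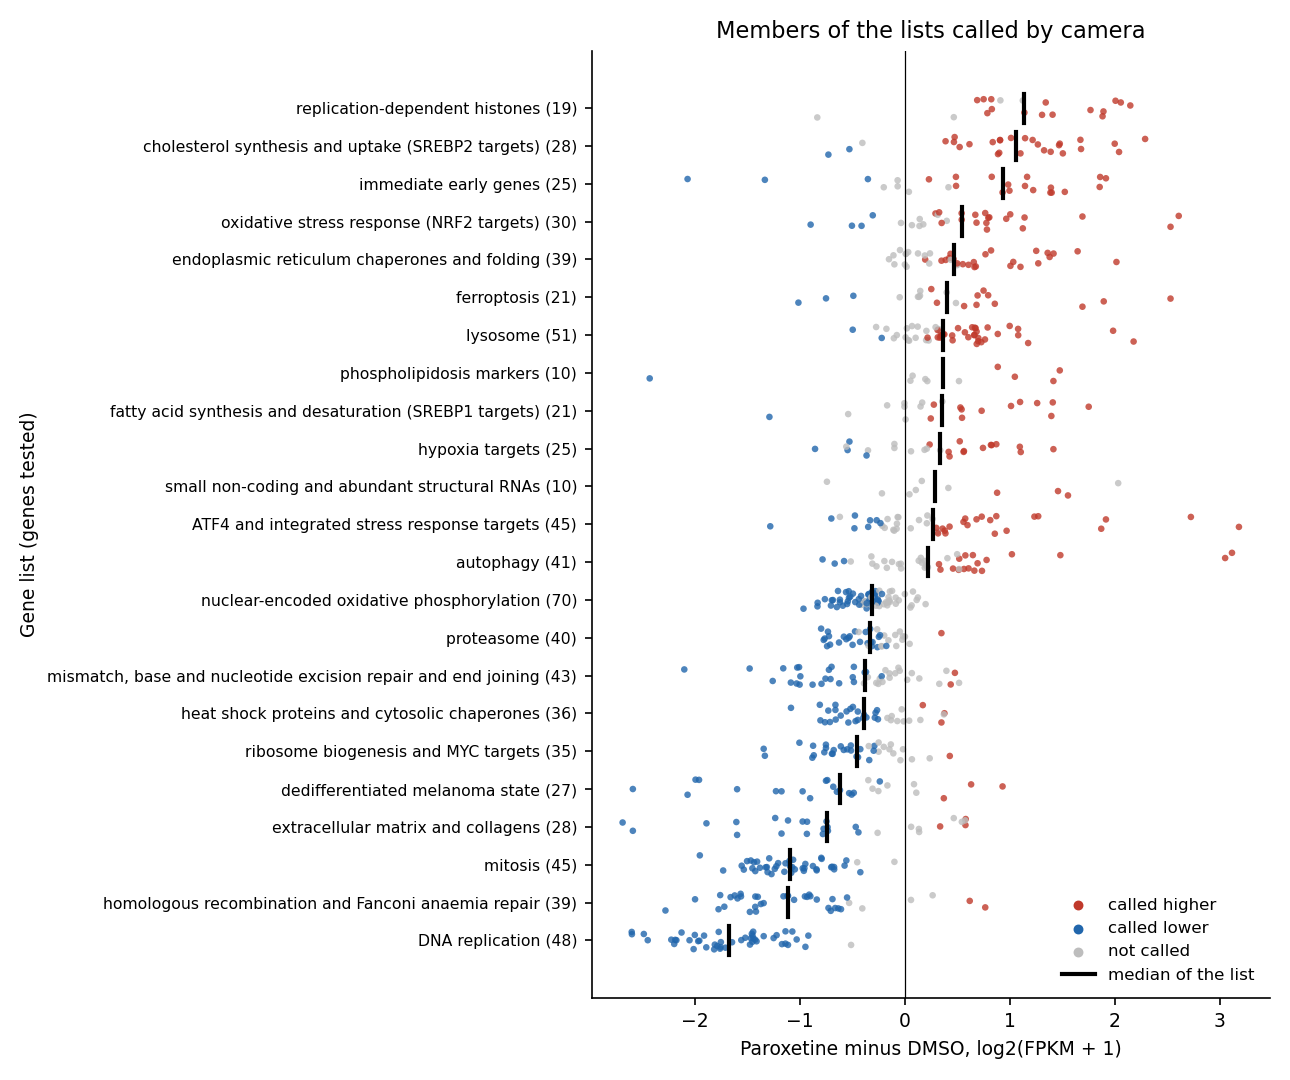
Each point is a tested member of 1 of the 23 lists called by camera, with its difference between paroxetine and DMSO in log2(FPKM + 1) on the x axis, red if called higher, blue if called lower and grey if not called. Black bars mark list medians, from -1.68 for DNA replication to 1.14 for replication-dependent histones.

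The title also names serotonin and histone serotonylation, the attachment of serotonin to histones. TGM2, the transglutaminase that can make this bond, fell from 59.8 ± 1.64 to 14.2 ± 0.967 FPKM (ENSG00000198959, chromosome 20, 38127387 to 38166578), a log2 change of -2.00 ± 0.08, and WDR5, a chromatin protein that binds the serotonylated histone, fell from 32.4 to 18.9 FPKM. SLC6A4, the serotonin transporter and the target of paroxetine, was below the filter, with 0 and 0.0220 FPKM in the DMSO libraries and 0.0941 and 0.0210 FPKM in the paroxetine libraries. SLC18A2, the vesicular monoamine transporter, was higher (5.26 to 8.37 FPKM; adjusted p = 0.0166), as was the serotonin receptor gene HTR7 (9.83 to 13.3 FPKM; adjusted p = 0.0456). The SLC18A2 call was lost without DMSO replicate 1 (adjusted p = 0.0683), DMSO replicate 2 (0.0810), paroxetine replicate 1 (0.0870) or paroxetine replicate 2 (0.0596), within 0.0115 to 0.0870 over all alternatives. The HTR7 call was lost without any of the same 4 libraries (0.160, 0.0558, 0.146 and 0.156), without the trend (0.0646), without a filter (0.0963) and with the replicate block (0.0582), within 0.0328 to 0.160. Of the 32 genes in the serotonin list only 5 passed the filter, SLC18A2, HTR7, TGM1, TGM2 and WDR5. The list therefore does not cover serotonin synthesis and breakdown and holds 1 receptor gene. As a list these 5 genes were not called (2 rose and 2 fell, the same adjusted over the list alone, camera adjusted p = 0.814), and their median (0.32) differed in sign from the mean (-0.29) and from the test (lower).

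Enzymes of histone methylation and acetylation moved both ways, with 11 higher and 9 lower of 53 (11 and 10 adjusted over the list alone, camera adjusted p = 0.850). These counts are near the share of all tested genes that were called (38.7%), as are those of the BCL2 family and interferon lists below. The histone deacetylase gene HDAC9 rose from 10.7 ± 0.204 to 43.0 ± 0.502 FPKM, and the methyltransferase genes SUV39H2 and NSD2 fell from 16.1 to 5.78 and from 54.99 to 32.5 FPKM. The median of this list was -0.03, its mean 0.04 and its test higher, and the median was above 0 after quantile normalization (0.02) and after rescaling without mitochondrial and abundant RNAs (0.02), which moved the median of all genes to 0.0387 as well.

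Pyroptosis is a lytic cell death in which gasdermin pores open the membrane. GSDME, a gasdermin gene, was at 16.04 ± 0.103 to 20.02 ± 1.79 FPKM (ENSG00000105928, chromosome 7, 24698351 to 24758113) and was not called (log2 change 0.30 ± 0.09, adjusted p = 0.0538). GSDMD was at 35.6 to 33.7 FPKM (adjusted p = 0.494). GSDMB, another gasdermin gene, named after its values were seen, was called higher (2.51 to 6.30 FPKM, adjusted p = 0.00844). Its call was not followed through the alternatives. GSDME passed the threshold with trimmed-mean scaling (adjusted p = 0.0491), quantile normalization (0.0448), a minimum of 5 FPKM (0.0434) and rescaling without mitochondrial and abundant RNAs (0.0287), within 0.0287 to 0.204 over all alternatives. HMGB1, a nuclear protein gene whose product is released by dying cells, fell from 409 to 138 FPKM, and IL1B, the cytokine gene interleukin-1 beta, fell from 15.01 to 4.28 FPKM. TXNIP, a thioredoxin-binding protein gene, rose from 11.4 ± 0.213 to 46.0 ± 0.602 FPKM and NLRP1, an inflammasome sensor gene, from 2.83 to 8.99 FPKM. Without paroxetine replicate 2 the NLRP1 call was lost (adjusted p = 0.0536; 0.00410 to 0.0536 over all alternatives). Of the 21 genes of pyroptosis and the inflammasome 5 rose and 5 fell (6 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.816, median -0.01, mean 0.05, test higher; the median was 0.0011 with trimmed-mean scaling and 0.04 after rescaling, where the median of all genes was 0.0387).

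Other lists of cell death and stress gave mixed counts. Of 30 BCL2 family and apoptosis genes 7 rose and 5 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.814). The pro-apoptotic gene BBC3 rose from 4.65 to 13.9 FPKM and the death receptor gene TNFRSF10B from 45.8 to 64.4 FPKM. The survival gene BCL2L1 fell from 51.3 to 28.7 FPKM and FADD from 30.0 to 20.5 FPKM. Of 30 p53 targets 11 rose and 4 fell (13 and 7 adjusted over the list alone, camera adjusted p = 0.149). CCNG1 rose from 87.4 to 140.0 FPKM and PLK2 fell from 49.2 to 20.04 FPKM. Of 30 targets of the oxidative stress factor NRF2 19 rose and 4 fell (20 and 4 adjusted over the list alone, median 0.54, camera adjusted p = 1.01e-05, adjusted p = 0.268 with an estimated correlation). FTL, the ferritin light chain, rose from 988 ± 0.225 to 3199 ± 315 FPKM, TXNRD1, thioredoxin reductase, from 118 to 238 FPKM and TKT, transketolase, from 331 to 646 FPKM. The 4 that fell were GSTM1, PRDX1, TALDO1 and TXN. Of 21 ferroptosis genes, which overlap that list, 11 rose and 3 fell, DHODH, CISD1 and IREB2 (the same adjusted over the list alone, median 0.40, camera adjusted p = 0.000526, adjusted p = 0.175 with an estimated correlation). SAT1, of polyamine breakdown, rose from 30.8 to 117 FPKM and the transferrin receptor gene TFRC from 64.8 to 109.7 FPKM. Of 5 genes of metallothioneins and zinc transport, MT2A fell from 1286 ± 185 to 313 ± 14.7 FPKM and MT1X from 28.6 to 5.37 FPKM. The zinc exporter gene SLC30A1 was higher (10.2 to 15.7 FPKM), a call lost without paroxetine replicate 1 (adjusted p = 0.0519; 0.00512 to 0.0519 over all alternatives). That list was not called (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.218).

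Inflammatory and interferon genes also went both ways. Of 28 targets of NF-kappaB and inflammatory cytokines 13 rose and 6 fell (13 and 9 adjusted over the list alone, camera adjusted p = 0.281). NFKB2, a subunit gene, rose from 60.04 ± 0.967 to 142 ± 5.42 FPKM, and the chemokine genes CXCL8, CXCL1 and CCL2 fell from 283 to 138, from 192 to 76.3 and from 82.6 to 20.3 FPKM. Of 40 interferon-stimulated genes 10 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.684, median 0.01, and -0.02 with quantile normalization). ISG20, an exonuclease gene, rose from 45.5 to 88.7 FPKM, TAP1, of antigen presentation, from 11.01 to 21.4 FPKM, and OAS3, of antiviral sensing, fell from 21.7 to 9.76 FPKM.

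Markers of melanoma states and of matrix were lower in part. Of 27 genes of the dedifferentiated melanoma state 18 fell and 3 rose, JUN, NT5E and PDGFRB, the last of which lost its call in 7 alternatives (20 and 3 adjusted over the list alone, median -0.62, camera adjusted p = 2.15e-06, adjusted p = 0.131 with an estimated correlation). Besides THBS1, CCN1, a matricellular gene, fell from 132 to 30.8 FPKM, CAV1, of caveolae, from 165 to 40.8 FPKM and FN1, fibronectin, from 315 ± 12.97 to 103 ± 0.0658 FPKM. Of 28 genes of extracellular matrix and collagens 18 fell and 3 rose, COL6A1, COL6A2 and FBN1 (18 and 4 adjusted over the list alone, median -0.74, camera adjusted p = 0.000244, adjusted p = 0.251 with an estimated correlation). COL5A2 fell from 58.8 to 18.7 FPKM and TIMP3, an inhibitor of metalloproteinases, from 180.0 to 82.7 FPKM. MITF, the master regulator of the melanocyte lineage, was at 7.48 to 5.67 FPKM and was not called (adjusted p = 0.0829). Of 15 genes of melanocyte differentiation and pigmentation 3 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.384), among them the rises of CITED1 (0.279 to 5.44 FPKM) and SOX10 (187 to 273 FPKM) and the fall of CDK2 (82.6 to 50.0 FPKM).

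Immediate early genes, the first to respond to growth and stress signals, were higher, with 17 of 25 that rose and 3 that fell, CCN1, MYC and MCL1 (18 and 3 adjusted over the list alone, median 0.93, camera adjusted p = 0.000140, adjusted p = 0.336 with an estimated correlation). EGR1 rose from 4.14 ± 0.196 to 17.6 ± 1.54 FPKM, ZFP36 from 9.65 to 37.7 FPKM and NR4A1 from 45.8 to 122 FPKM. The outputs of MAP kinase signalling, which A375 cells drive through mutant BRAF, were split, with 8 higher and 8 lower of 26 (9 and 10 adjusted over the list alone, camera adjusted p = 0.935). DUSP6 fell from 91.8 to 41.1 FPKM, CCND1, cyclin D1, from 215 to 94.1 FPKM and the receptor gene EPHA2 from 138 to 62.2 FPKM, and the list's median (-0.01) was above 0 with quantile normalization and after rescaling (0.04 each), the latter with a median of all genes of 0.0387.

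Genes of energy metabolism were lower in the mitochondrial respiratory chain. Of 70 nuclear genes of oxidative phosphorylation 43 fell and 0 rose (49 fell adjusted over the list alone, median -0.32, camera adjusted p = 3.90e-09, adjusted p = 0.272 with an estimated correlation). The respiratory chain genes NDUFA7, NDUFV2 and NDUFA4 fell from 84.8 to 49.6, from 146 to 92.6 and from 60.7 to 37.4 FPKM, and COX8A from 523 ± 15.1 to 357 ± 9.21 FPKM. Of 13 protein genes encoded in mitochondrial DNA 4 fell and 1 rose, MT-ND1 (the same adjusted over the list alone, camera adjusted p = 0.333). MT-CO3 fell from 9399.7 to 5168 FPKM. That list was called lower without paroxetine replicate 2 (adjusted p = 0.0446; 0.0446 to 0.884 over its alternatives), and the MT-ND1 call was lost without DMSO replicate 1 (0.0633) or DMSO replicate 2 (0.0744; 0.00405 to 0.0744 over all alternatives). Of 24 glycolysis genes 14 fell and 5 rose (15 and 5 adjusted over the list alone, camera adjusted p = 0.0943, 0.0452 with no filter and 0.0452 to 0.380 over its alternatives). The glucose transporter gene SLC2A1 fell from 154 to 84.4 FPKM. SLC2A3, another glucose transporter gene, rose from 16.4 to 45.4 FPKM, as did the isoenzyme genes ALDOC (29.8 to 99.7 FPKM) and ENO2 (51.7 to 102 FPKM). Of 25 hypoxia targets 13 rose and 4 fell, SLC2A1, ANGPTL4, PFKFB3 and PFKFB4 (14 and 4 adjusted over the list alone, median 0.34, camera adjusted p = 0.0113, adjusted p = 0.336 with an estimated correlation). NDRG1 rose from 53.5 to 116 FPKM and BHLHE40 from 13.2 to 29.4 FPKM.

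Of 78 cytosolic ribosomal protein genes 7 were called higher and 2 lower, and 0 of either adjusted over the list alone. The list was not called (camera adjusted p = 0.0513, median log2 change 0.09), but was called higher with trimmed-mean scaling (0.0391, median 0.09), with a pseudocount of 0.1 (0.0437, median 0.09), after rescaling (0.00117, median 0.14) and without paroxetine replicate 1 (5.93e-05, median 0.14), within 5.93e-05 to 0.592 over its alternatives. Of 14 genes of xenobiotic metabolism 5 rose and 1 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.253). TIPARP, a gene of the PARP family, rose from 31.5 to 93.7 FPKM and CYP1A1, a cytochrome P450 gene, from 1.85 to 6.39 FPKM, and GSTP1, of glutathione conjugation, fell from 382 to 257 FPKM. Markers of other cell types gave no shared direction. Of 6 epithelial markers 4 fell, KRT14, KRT7, KRT8 and KRT18, and 2 rose, DSP and CLDN4 (the same adjusted over the list alone, camera adjusted p = 0.220). Of 5 blood and immune markers 1, CORO1A, fell (7.03 to 1.28 FPKM; the same adjusted over the list alone), and the median (1.38) and the test (lower, camera adjusted p = 0.970) differed in sign. The fibroblast and endothelial lists had 3 members each above the filter, too few to test, and among them PDGFRB was at 2.67 to 4.73 FPKM (adjusted p = 0.0485; 0.0439 to 0.187 over all alternatives) and ENG at 25.6 to 18.6 FPKM (adjusted p = 0.00978; 0.00677 to 0.0639).

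**Figure D3:**
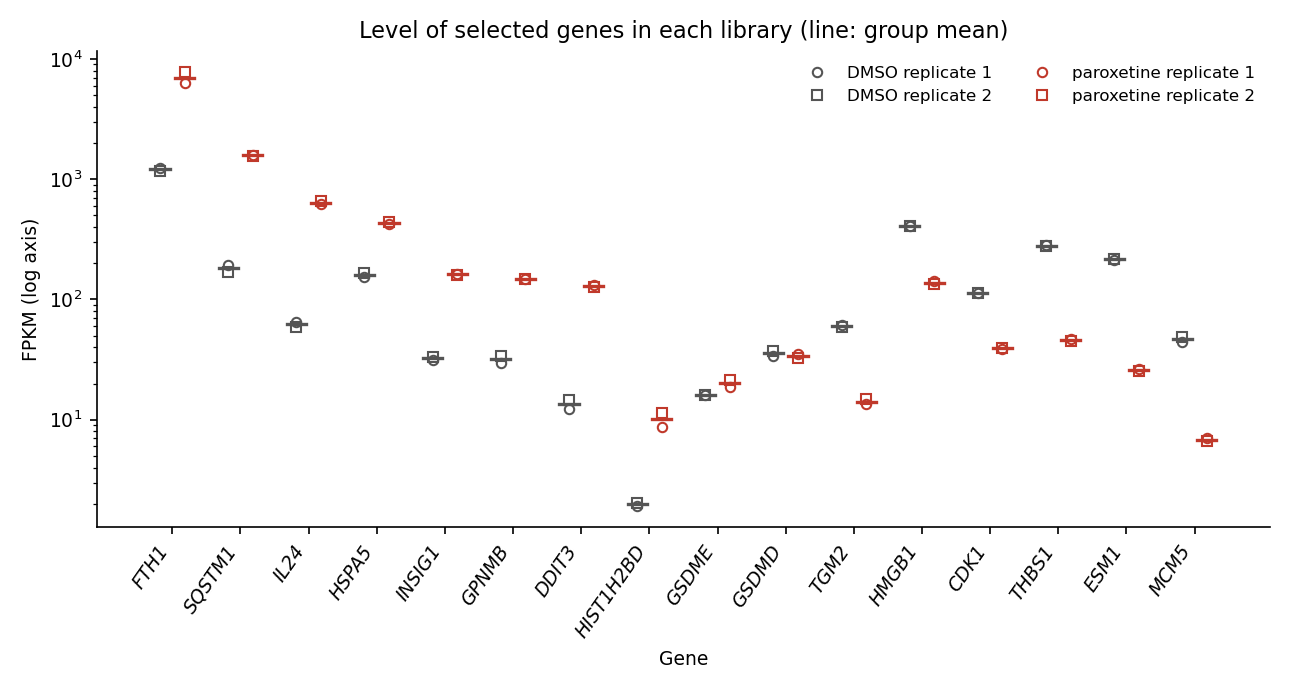
FPKM of 16 genes on a log axis in each of the 4 libraries, with circles for replicate 1, squares for replicate 2, grey for DMSO and red for paroxetine, and lines at the group means. The values of the groups overlap for GSDMD and lie apart for the other 15 genes.

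Of the 40 lists tested with camera, 13 were called higher and 10 lower at a preset inter-gene correlation of 0.01, and with an estimated correlation 0 were called, the smallest adjusted p being 0.131. Camera compares a list with all other genes, so a list can be left uncalled although single members changed.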

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

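No test in this part was chosen only after the result was seen: the alternatives were fixed before the data were examined. Requiring a 2-fold change left 572 genes higher and 684 lower, a stricter definition by construction. Leaving out 1 library left 1442 to 1539 genes higher and 1773 to 2221 lower, where fewer samples give less power and the lone sample of an arm is assumed to vary like the other group. Camera with an estimated correlation called 0 lists higher and 0 lower, so no list call held in that setting. The estimate lay below the preset 0.01 for some called lists (lysosome -0.0179) and above it for others (immediate early genes 0.183). For DNA replication the estimate was 0.0125, near the preset value, yet camera gave adjusted p = 0.131. A raised correlation therefore does not account for all of these losses. With an estimated correlation camera uses the 2 residual degrees of freedom and so has little power here. The losses therefore say little about correlation between genes. Fry, which does not compare with other genes, kept all 13 higher and 10 lower calls. The replicate block gave 2492 genes higher and 2883 lower, changed no list call and ended 3 named-gene calls, HTR7 and PDGFRB among them. The balance of 2811 higher and 3184 lower depends on scaling: 3145 and 2814 after rescaling without mitochondrial and abundant RNAs, which multiplies each library by 1 constant and so by construction shifts genes 1 way (median of all genes -0.0047 before and 0.0387 after), 2988 and 2911 with quantile normalization, and 2847 and 3142 with trimmed-mean scaling. Of the 166 named genes 152 could be tested in all 12 alternatives and 14 in 1 fewer, and 149 kept their call wherever tested, 17 changed it in at least 1, and 0 changed direction.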

Other observations

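All tests in this part were chosen only after the result was seen, except the rules for opposite-strand and pseudogene reads, which were written before their values were computed though examples had been seen. Golgi genes were among the rises: GOLGA2, a Golgi matrix gene, rose from 36.0 to 100.4 FPKM, GOLGA3 from 14.5 to 45.4 FPKM, SEC24D, of transport vesicles, from 14.7 to 47.7 FPKM and the retrieval receptor gene KDELR3 from 13.8 to 41.4 FPKM. A list of Golgi and transport genes without the 10 genes that prompted it had a median log2 change of 0.465, with 38 of 58 higher and 3 lower (camera adjusted p = 5.57e-10 in limma, adjusted p = 0.115 with an estimated correlation). Actin and tubulin genes fell among abundant genes, ACTB from 1692 to 597 FPKM, TUBA1B from 1211 to 416 FPKM and TPM1 from 164 to 72.4 FPKM, and the list without ACTB and TUBA1B had a median of -0.43, with 29 of 43 lower and 1 higher (camera adjusted p = 6.26e-08, adjusted p = 0.198 with an estimated correlation).

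Targets of the growth regulators YAP and TAZ were lower, CCN2 from 37.8 to 8.99 FPKM, CRIM1 from 125 to 34.4 FPKM and AXL from 157 to 66.6 FPKM. Without the 4 prompting genes the median was -0.59, with 9 of 17 lower and 2 higher (camera adjusted p = 0.00158, adjusted p = 0.198 with an estimated correlation), and 3 of the 17 belong to the fixed lists. MHC class II genes of antigen presentation were lower, HLA-DRA from 141 to 64.7 FPKM, CD74 from 656 to 402 FPKM and HLA-DPA1 from 103 to 52.8 FPKM, and without the first 2 the median was -0.68, with 6 of 7 lower (camera adjusted p = 0.00372, adjusted p = 0.198 with an estimated correlation). The nutrient-sensing genes RRAGD (3.90 to 13.4 FPKM), RRAGC (15.7 to 40.2 FPKM), FLCN (6.12 to 17.1 FPKM) and FNIP1 (6.003 to 16.4 FPKM) rose. Of all 20 genes of the Rag, folliculin and GATOR complexes 7 were higher and 3 lower (camera adjusted p = 0.118), and without the 5 prompting genes, these 4 and FNIP2, the other 15 had a median of -0.0182, with 3 higher and 3 lower (camera adjusted p = 0.981). The full lists had been tested before the prompting genes were removed, so these results are not independent evidence.

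Histone genes rose while replication genes fell. Fewer cells in S phase, which would lower both, is left open. The 9 histone genes not known to make polyadenylated transcripts outside S phase had a median log2 change of 1.31 ± 0.24 (SE over genes). All 9 were above 1 FPKM in both paroxetine libraries, and none reached 1 FPKM in both DMSO libraries. They thus passed the filter through the paroxetine libraries, which favours a rise, so this median cannot decide the question. In addition, 0 of them were at a mean of 5 FPKM or more, and the more abundant histone genes that rose can be transcribed outside S phase. More RNA without a poly(A) tail is a candidate explanation. The list of small non-coding and abundant structural RNAs, fixed as a check on RNA depletion, was called higher by camera (adjusted p = 0.0226, 0.268 with an estimated correlation). In it MALAT1, NEAT1 and MT-RNR2 rose, 0 fell and 7 of 10 were not called. The 32 tested genes annotated as small RNAs had a median of 0.0136 with an SD of 1.302, with 2 called higher and 6 lower. Many are 7SK and 7SL pseudogenes by symbol, and only 6 were at a mean of 5 FPKM or more. Presence and absence of this effect therefore cannot be told apart here.

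Genes that share exons or sequence with a raised gene were often raised. Of genes overlapped on the opposite strand by a raised and more abundant gene, 34 had a median log2 change of 0.70 against 0.36 in 46 neighbours without overlap, a difference of 0.34 (two-sided permutation p = 0.0459, 95% bootstrap interval -0.0746 to 0.632). The interval includes 0 and 14 of 34 against 16 of 46 genes were called higher, so counting of the opposite strand may contribute but the evidence is borderline. Processed pseudogenes followed their parents with a Spearman rho of 0.419 over 318 pairs (95% bootstrap interval 0.313 to 0.516, permutation p = 1e-05, the smallest these permutations can give), and 0.382 without FTH1 pseudogenes. The pairs have 226 distinct parents and 85 are of ribosomal protein genes (rho 0.456 without these). Pairs were resampled as if independent, so the interval may be too narrow and the p too small. Shared reads are a likely source of part of the pseudogene calls, of which 46 of 64 had the sign of the parent.

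Haemoglobin transcripts differed between libraries: HBB was at 1.08 and 33.1 FPKM in the DMSO libraries and 32.0 and 96.9 FPKM in the paroxetine libraries. The 30.6-fold ratio between the DMSO libraries exceeds the 3.77-fold ratio of the group means, so HBB varied widely without paroxetine. That ratio rests on DMSO replicate 1 at 1.08 FPKM, and the ratio between the paroxetine libraries, 3.03, lies below 3.77. A part played by paroxetine is therefore not excluded. Blood RNA from outside the culture could explain the differences between libraries. Of 3 other blood transcripts at a mean of 1 FPKM or more, 2 were, like HBB, lowest in DMSO replicate 1 and highest in paroxetine replicate 2. They were HBA1 and HBA2, but not LYZ, and HBE1, an embryonic form with the same order, is not counted. The middle libraries were not compared, and its presence and absence cannot be told apart here.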
